A study of Mus musculus with 6 samples.

How the data were processed

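The series holds m6A-seq of male mouse germ cells at postnatal day 35, with 1 IP and 1 input library for each of WT, ClpP cKO and ClpX cKO. Per the labels' protocols, 1.3 ug of total RNA went into library construction. The 6 samples were put in 6 groups from their titles. The data used here were 2 tables of the authors' own comparisons, ClpP cKO against WT and ClpX cKO against WT, each resting on 4 libraries. The build is GRCm38 (mm10), per the submitters' processing notes. The aligner, the peak caller and their settings are not given in the sources used here.

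Per the file headers, each table lists 1 peak per line, with its blocks along a transcript, the p-value of the peak, and scores that are the log10 of that p-value and of its adjusted form. The authors also deposited a fold enrichment of IP over input for each peak, a linear ratio, given once for all libraries of a table. Per the file headers, the difference between genotypes is a log2 fold change with the score log10 of its p-value and of its adjusted p-value. How the authors normalised libraries for depth is not given in the sources used here, and a factor that differs between IP libraries would shift all log2 fold changes of a table together. The deposited adjusted p-values were checked against a Benjamini-Hochberg adjustment of the deposited p-values over the table, and 99.39% (ClpP) and 99.32% (ClpX) lay within 0.05 on the log10 scale. The largest p-value of a difference was 0.778 in both tables. The direction of the log2 fold change is stated nowhere else than in each table's naming of the knockout before WT. All listed peaks had a peak adjusted p under 0.05, so sites without a called peak are not analysed here.

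Depth per library is unknown, since read counts were not used here, and no interval that needs it is given. Exact binomial (Clopper-Pearson) 95% intervals of shares treat peaks as independent, which peaks of 1 gene are not, and leave out the spread between animals. With 1 library per group no test across replicates was possible, so no p-value across replicates was computed here. The authors' calls, and the alternatives that adjust their p-values or call peaks anew, compare libraries only.

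A peak was called where the authors' adjusted p was under 0.05, and its direction was read from the sign of its log2 fold change. Gene names are those of the tables. For gene lists, a gene took the value of its peak with the smallest p for the difference, so its ClpP and ClpX values may come from different sites. A list's median was placed among 10000 random lists of the same size matched on the number of peaks per gene, capped at 6, as a description of these libraries. Random lists were not matched on expression, which the tables do not give. The 18 lists covered ClpXP and mitochondrial proteostasis, the integrated stress response, the respiratory chain, mitochondrial dynamics, mTORC1 signalling, autophagy, meiotic recombination, meiotic division, the piRNA pathway, spermatogonia, spermatids, Sertoli cells, other somatic cells of the testis, m6A regulators, translation, ubiquitin and proteasome, apoptosis, and fatty acid oxidation with the TCA cycle. In simulated data, lists of 50 genes shifted by 1 on the log2 scale left the central 95% in 100 of 100 draws on the 13334 genes of the ClpP table and 94 of 100 on the 13085 genes of the ClpX table. Lists of 20 genes did so in 83 and 65, and unshifted lists of 20 in 9 and 2. With a shift of 0.5, lists of 50 did so in 52 and 55 draws and lists of 20 in 29 and 32. A list inside the central 95% may therefore still be shifted by that much.

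Named genes followed a rule per comparison: Clpp and Clpx; the 8 genes of top rank in each direction by adjusted p, ties by absolute log2 fold change, leaving out predicted genes; up to 4 called members of each list by the same rank; every called m6A regulator; and up to 5 peaks per direction called in both comparisons. A gene that the rule takes is not reported here. The mitochondrial peaks beyond that rule were chosen after their values were seen. Groups, lists, thresholds, this rule and the alternatives other than those named below were chosen before the data were examined.

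Peaks of both tables were paired by overlap of at least 1 base on the same strand, block by block, with bedtools 2.31.1, keeping best mutual pairs. Unchanged knockouts were simulated 200 times: each peak's error came from its p and log2 fold change, taken as a median over peaks of like support, with WT and knockout given equal shares of the variance and the WT part common to both comparisons. Peak positions were set against RefSeq gene spans of the same build, matched by symbol, which placed 12221 of 13334 genes (ClpP) and 12020 of 13085 (ClpX). A planned search for the m6A sequence motif and a planned split by UTR and coding part were not run, since no genome sequence or transcript structure was used here. Of the peaks, 10.82% (ClpP) and 11.6% (ClpX) share bases with another peak of the same table on either strand, and those are uncertain as to their gene.

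Alternatives were a stricter adjusted p of 0.01, an absolute log2 fold change of at least 1, an unadjusted p under 0.05, a fold enrichment of at least 2, centring on the median of all peaks, counting genes, averaging all peaks of a gene, unmatched random lists, and other definitions of overlap and position. After seeing the data, more were added: p-values doubled before adjustment, leaving out peaks that share bases, centring within 5 equal groups of fold enrichment, random lists also matched on fold enrichment or on peak support, and calling peaks anew. Centring by itself changed only the direction read for called peaks, so peaks were also called anew at the authors' limit. There the error of a called peak came from its own p and log2 fold change. That of another peak was the larger of its own and the median over peaks of like support, because in the eighth of peaks nearest 0 the own error was 0.258 (ClpP) and 0.2787 (ClpX) times that median. Pooled errors gave that median to every peak. In the closing section, mitochondrial peaks were set against 10000 random sets of as many matched nuclear peaks. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.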

Results

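N6-methyladenosine (m6A) was mapped by antibody capture of RNA followed by sequencing (m6A-seq) in male mouse germ cells described as spermatocytes, taken at postnatal day 35. In this assay an immunoprecipitated (IP) library holds the captured RNA and an input library holds the RNA before capture. The 6 libraries covered 3 genotypes: wild type (WT), a germ-cell knockout of ClpP and a germ-cell knockout of ClpX, both made with Stra8-Cre. ClpP is the proteolytic subunit and ClpX the ATP-dependent unfoldase of the ClpXP protease of the mitochondrial matrix. Each of the 6 groups held 1 library, so no value below has a replicate error, and no difference has a replicate check. The values come from the authors' own comparisons of each knockout (cKO) with WT, which gave 24127 peaks on 13334 genes for ClpP and 23681 peaks on 13085 genes for ClpX. Read counts per library were not used here, so the depth is unknown.

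The study asked about mitochondrial function in control and knockout spermatocytes, and its title names mTORC1 signalling and meiosis. A positive log2 fold change is read here as higher m6A enrichment (IP over input) in the knockout, a direction taken only from each table naming the knockout first. A peak is called higher or lower where the authors' adjusted p for the difference was under 0.05. That call compares 1 knockout with 1 WT set of libraries, not the conditions in general. Coordinates are on GRCm38 (mm10).

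The targeted genes were looked at first. Clpx on chromosome 9 (plus strand, gene span 65294251 to 65330658) carried a peak at 65329852 to 65330240 in the ClpP comparison, with a log2 fold change of 0.38 in the authors' deposited table, and at 65329882 to 65330240 in the ClpX comparison, with 0.55; neither was called. Clpp on chromosome 17 (gene span 56990264 to 56996371) had a peak at 56996039 to 56996188 in the ClpX comparison alone, with a log2 fold change of 1.70 and an adjusted p of 0.069 in the authors' deposited table, so it was not called. Enrichment is a ratio of IP to input, and these values check the genotype labels only weakly.

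In ClpP cKO against WT, peaks on mitochondrially encoded RNAs ranked first among the increases, and peaks on Fhl4 and Ldhc first among the decreases. The rank is by adjusted p, not by the size of the change. The mitochondrial ribosomal RNAs mt-Rnr1 (positions 756 to 905) and mt-Rnr2 (1094 to 1422) had log2 fold changes of 1.67 and 1.65 in the authors' deposited table, with fold enrichments of 1.14 and 1.87. The complex I subunits mt-Nd2 (4418 to 4951) and mt-Nd4 (11305 to 11544) had 0.62 and 0.84, with fold enrichments of 3.31 and 1.99. These 2 log2 fold changes lay below the median of all peaks called higher, 1.32. Prm1, a protamine that packs sperm DNA, was called higher at 1.29 (chromosome 16, 10796326 to 10796469), and Pabpc1, a poly(A)-binding protein, at 1.22 (chromosome 15, 36595811 to 36596242) in the authors' deposited table. The Prm1 peak was weakly enriched, at 1.73, against 3.43 for Pabpc1. Ldhc, the lactate dehydrogenase of the male germ line, was called lower at -1.10 (chromosome 7, 46861342 to 46866473), and the LIM-domain gene Fhl4 at -0.75 (chromosome 10, 85097541 to 85099332) in the authors' deposited table. In all, 1626 peaks on 1433 genes were called higher and 3096 peaks on 2649 genes were called lower, so 34.43% of the 4722 called peaks were higher (exact binomial 95% interval 33.08 to 35.81, over peaks), or 65.57% if the ratio runs the other way.

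The other top-ranked increases for ClpP were Ubb, a polyubiquitin gene, at 0.85 and Serf1 at 1.58 in the authors' deposited table. Both peaks were weakly enriched, with fold enrichments of 1.47 and 1.57. Among the top-ranked decreases the authors' deposited table gave -0.92 for Csl, -0.97 for the fructose transporter Slc2a5, -0.72 for the ubiquitin ligase Rnf139, -0.71 for Gykl1, -0.73 for Atxn7l3b and -0.63 for the glycerol kinase Gk2. The peaks of Rnf139 and Atxn7l3b share bases with a peak of another gene and cannot be assigned to 1 of them. Peaks called higher had a median log2 fold change of 1.32 (10th to 90th percentile 0.60 to 2.48) and a median fold enrichment of 3.83. Peaks called lower had a median of -0.84 (-1.65 to -0.42) and a median fold enrichment of 7.98.

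Of the 18 gene lists fixed before the data were examined, the meiotic recombination and synapsis list was among the higher ones in ClpP cKO. Of its 41 measured genes 11 were called higher and 7 lower, with a median log2 fold change of 0.40, at percentile 97.15 of 10000 random lists with the same numbers of peaks per gene. That percentile lies just inside the central 95%, and it was 97.84 when all peaks of a gene were averaged and 97.59 against unmatched random lists. Sycp2, a lateral element protein of the synaptonemal complex, was called higher at 2.54 in the authors' deposited table, while Cntd1 at -1.14, the checkpoint kinase Atr at -0.72 and the histone variant H2afx at -0.74 were called lower. The meiotic division list had 4 higher and 7 lower of 27 genes (percentile 85.32), with Mad2l1 of the spindle checkpoint at 3.01, the separase Espl1 at -1.01, the chaperone Hspa2 at -0.25 and Plk4 at -0.59 in the authors' deposited table. The list named for spermatogonia had 1 higher and 2 lower of 14 genes and a median of 0.80 (percentile 98.03, but 85.57 with all peaks of a gene averaged). Its called members in the authors' deposited table were Zbtb16 at 1.30, Tex101 at -0.43 and Gfra1 at -2.68, the last sharing bases with another gene's peak. Whether each member marks spermatogonia in these cells was not tested. Markers of Leydig, peritubular, endothelial and immune cells stood higher still, with a median of 1.13 over 17 genes (percentile 99.92), although only Myh11 at 1.73 and Col1a1 at 1.13 were called in the authors' deposited table. The Sertoli cell list had 2 higher and 4 lower of 20 genes (percentile 47.47), including Clu at 0.86, Ctsl at -1.02, Tjp1 at -1.80 and Inha at -1.52 in the authors' deposited table.

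Mitochondrial and nutrient-sensing lists showed calls both ways in ClpP cKO. The nuclear-encoded respiratory chain list had 5 higher and 4 lower of 22 genes (median 0.42, percentile 96.87), with the succinate dehydrogenase subunit Sdhd at 1.29 and Cox8c at -0.50, Ndufa2 at -0.66 and Uqcrfs1 at -0.37 in the authors' deposited table. ClpXP and mitochondrial proteostasis genes had 2 higher and 2 lower of 19 (percentile 55.36): the mitochondrial chaperone Hspa9 at 1.04, Grpel1 at 0.49, the prohibitin Phb2 at -1.29 and the protease Yme1l1 at -0.78 in the authors' deposited table. Mitochondrial dynamics genes had 5 higher and 7 lower of 22 (percentile 13.55), with the mitophagy receptor Bnip3l at 2.99, the polymerase Polg at 1.07, the fusion protein Mfn2 at -0.90 and Pld6 at -0.65 in the authors' deposited table. Of 48 measured mTORC1 genes 4 were called higher and 9 lower, with a median of -0.19 (percentile 49.31). Mtor itself was called lower at -0.85 (chromosome 4, 148553096 to 148557683) in the authors' deposited table, as were Rragc at -1.56 and Stk11 at -1.63, while Mios was called higher at 0.66. Autophagy genes had 4 higher and 7 lower of 30 (percentile 26.46), with Tax1bp1 at 1.46, Wipi2 at -0.88, Map1lc3b at -1.0 and Atg12 at -0.92 in the authors' deposited table. Fatty acid oxidation and TCA cycle genes had 4 of each of 23 (percentile 82.48), with Dld at 0.99, Pdha2 at -0.53, Cs at -0.97 and Slc25a20 at -1.12 in the authors' deposited table.

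Of 25 measured genes of the m6A machinery 2 were called higher and 9 lower in ClpP cKO, with a median of -0.35 at percentile 31.25. All 3 cytoplasmic YTHDF readers were among them in the authors' deposited table, with Ythdf1 at -0.86, Ythdf2 at -0.71 and Ythdf3 at -0.94. The writer subunits Virma at -0.98, Rbm15b at -0.93 and Rbm15 at -0.25, the demethylases Fto at -0.82 and Alkbh5 at -0.92, and Prrc2a at -0.81 completed the decreases in the authors' deposited table, while Ythdc1 at 1.33 and Cbll1 at 0.60 were called higher. The peaks of Rbm15b, Ythdc1 and Cbll1 share bases with a peak of another gene. Translation factors had 6 higher and 17 lower of 39 (median -0.30, percentile 30.89), with Pabpc2 at -0.68, Eef1d at -1.34 and Eif4a2 at -1.35 in the authors' deposited table. Spermatid genes had 14 higher and 20 lower of 55 (percentile 65.75), with the sheath protein Akap3 at -0.87 and Pgk2 at -0.81 in the authors' deposited table. The piRNA list had 4 higher and 5 lower of 14 (percentile 72.26), with Tdrd6 at -0.53, Henmt1 at -1.39 and Tdrd5 at -0.80 in the authors' deposited table. Integrated stress response genes had 1 higher and 4 lower of 19 (percentile 54.12), with the kinase Eif2ak1 at -0.88, Sesn2 at -0.86, Ppp1r15a at -1.87 and Psat1 at -0.64 in the authors' deposited table. Ubiquitin and proteasome genes had 9 higher and 5 lower of 38 (percentile 82.83), including Psmc2 at 0.84 and Cul1 at -1.07 in the authors' deposited table. Apoptosis genes had 2 higher and 5 lower of 20 (percentile 30.37), with Birc2 at 0.81, Bcl2l1 at -0.79, Mcl1 at -0.68 and Mdm4 at -0.97 in the authors' deposited table.

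By chance 0.9 of the 18 lists would lie outside the central 95% of random lists, and for ClpP 2 lay above it and 0 below. Among peaks with an absolute log2 fold change of at least 1 the numbers were 1085 called higher and 1122 lower.

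In ClpX cKO against WT, peaks on mitochondrial transcripts again ranked first by adjusted p among the increases, and most called peaks were higher as the authors scaled the values. All 8 mitochondrial peaks were called higher in the authors' deposited table, among them the complex I subunits mt-Nd5 (positions 12340 to 13565) at 2.74, mt-Nd4 (10676 to 11544) at 2.29, mt-Nd1 (2841 to 3647) at 2.15 and mt-Nd2 (3914 to 4951) at 1.77, and cytochrome b, mt-Cytb (14614 to 15259), at 2.39. The nuclear genes of top rank were the linker histone gene Hist1h1a at 1.12 (chromosome 13, 23763666 to 23764347) and the beta-tubulin gene Tubb4b at 1.64 (chromosome 2, 25222995 to 25223536) in the authors' deposited table. Called lower were Fhl4 at -0.48, the endoplasmic reticulum chaperone Hspa5 at -0.79 (chromosome 2, 34775568 to 34776468), Ldhc at -1.04 and the inositol transporter Slc5a3 at -1.49 (chromosome 16, 92076741 to 92079679) in the authors' deposited table. In all, 3567 peaks on 2901 genes were called higher and 1185 peaks on 1102 genes lower, so 75.06% of the 4752 called peaks were higher (exact binomial 95% interval 73.81 to 76.29, over peaks), or 24.94% if the ratio runs the other way. This majority depended on the scaling and on the error given to a peak, in alternatives added after the data were seen. After the median of all peaks, 0.239, was subtracted and peaks were called anew, 56.65% were higher. With errors also pooled over peaks of like support 41.88% were higher, while pooled errors without that subtraction gave 59.93%. Each of these shares is to be subtracted from 100% if the ratio runs the other way.

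**Figure D1:**
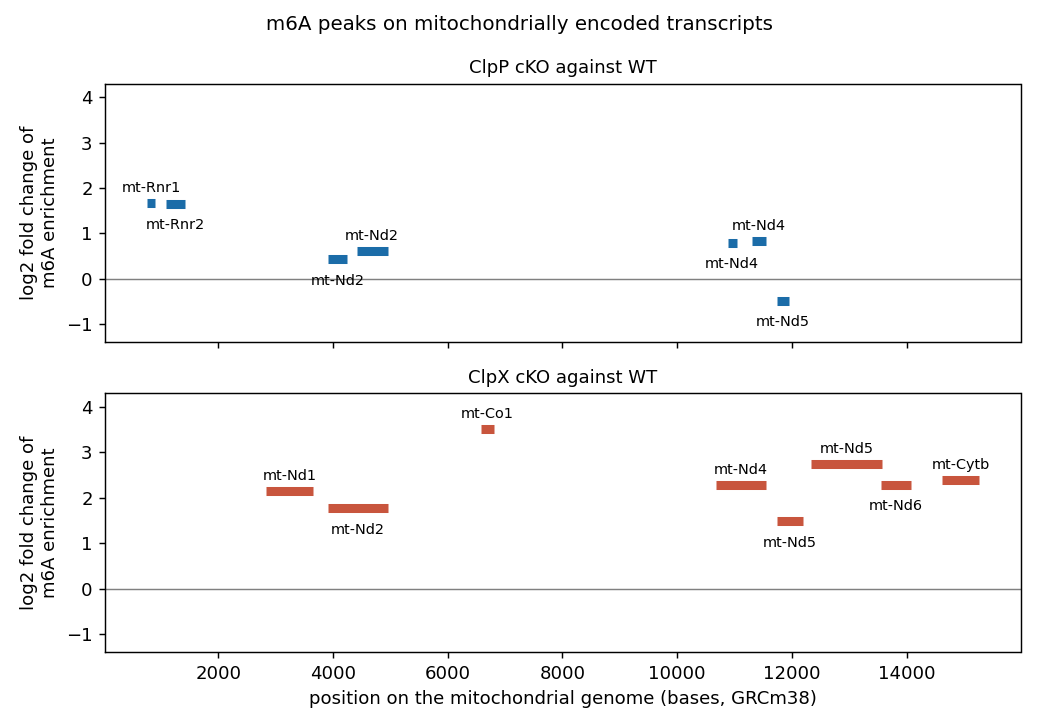
Log2 fold change of m6A enrichment (y axis, no unit) of each peak against its position on the mitochondrial genome (x axis, bases), for ClpP cKO (top) and ClpX cKO (bottom) against WT, from the authors' deposited tables. Each bar spans 1 peak; 6 of 7 peaks lie above 0 for ClpP, with mt-Nd5 at -0.48, and 8 of 8 for ClpX, from 1.48 to 3.51.

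The remaining top-ranked decreases for ClpX in the authors' deposited table were Gk2 at -0.56, the elongation factor Eef1a1 at -0.66, the long noncoding RNA Malat1 at -0.67 and Arl4a at -0.58. The peaks of mt-Nd5 and mt-Nd6 (2.28) in the authors' deposited table lie on opposite strands and share bases, and those of Eef1a1, Malat1, Twnk, Lamtor1, Sqstm1, Atg9a, Cbll1 and Diablo share bases with a peak of another gene, so their gene is uncertain. Hist1h1a and Tubb4b belong to families of near-identical genes, and reads of one member may have been assigned to another. Increases were concentrated in weakly enriched peaks: the median log2 fold change fell from 0.81 over the 4737 peaks of lowest fold enrichment (1.12 to 3.79) to -0.26 over the 4736 of highest (17.1 to 220). Peaks called lower had a median fold enrichment of 16.2, against 4.28 for those called higher. For ClpP the corresponding medians were 0.17 and -0.17. Some large ClpX values named below came from weakly enriched peaks. Their fold enrichments in the authors' deposited table were 1.71 (Tsc2), 1.76 (Clpb), 1.53 (Parp1), 1.49 (Hspa9), 1.35 (Eif3g) and 1.41 (Insl3). Those of C1qc (4.27) and Chac1 (23.7) were higher.

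**Figure D2:**
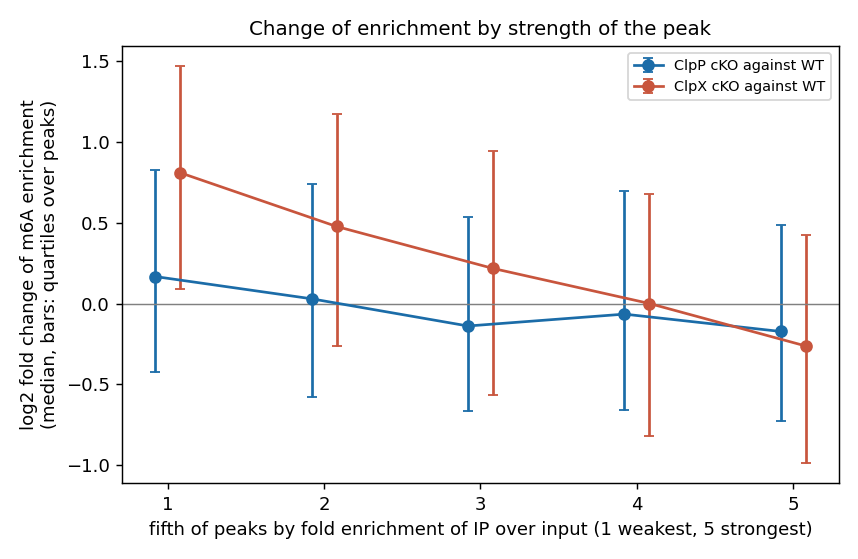
Median log2 fold change of m6A enrichment (y axis) in 5 equal groups of peaks ordered by fold enrichment of IP over input (x axis, 1 weakest to 5 strongest), with bars for the quartiles over peaks. The ClpX medians run from 0.81 to -0.26 and the ClpP medians from 0.17 to -0.17.

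Markers of Leydig, peritubular, endothelial and immune cells had the highest median of the 18 lists in ClpX cKO as well, 1.81 over 18 genes with 5 called higher and 0 lower (percentile 99.99). This list has the lowest median in both comparisons if the ratio runs the other way. The Leydig cell genes Insl3 at 2.01 and Cyp17a1 at 2.11, the collagen gene Col1a1 at 1.81 and the complement gene C1qc at 3.50 were called higher in the authors' deposited table, the Insl3 peak sharing bases with another gene's. Sertoli cell genes had 2 higher and 3 lower of 20 (percentile 17.95), with Clu at 1.24, Vim at 1.87, Inhbb at -1.19 and Sox9 at -2.55 in the authors' deposited table. The list named for spermatogonia had 4 higher and 1 lower of 14 (percentile 46.83), with Dmrt1 at 1.91, Stra8 at 1.04, Zbtb16 at 0.94 and Etv5 at -1.69 in the authors' deposited table. Spermatid genes had 27 higher and 4 lower of 54 (median 0.62, percentile 86.72, and 27.38 matched on fold enrichment), with the protamine Prm2 at 1.11, Tcp11 at 1.30 and Smcp at 1.11 in the authors' deposited table. Matching on fold enrichment was added after the data were seen.

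Calls in the mitochondrial lists were nearly all increases in ClpX cKO, as were 75.06% of called peaks in general (24.94% if the ratio runs the other way). ClpXP and mitochondrial proteostasis genes had 5 higher and 0 lower of 21 (median 0.93, percentile 95.63, and 79.22 matched on fold enrichment), with the disaggregase Clpb at 2.80, Hspa9 at 2.57, Phb2 at 1.58 and Grpel1 at 1.27 in the authors' deposited table. Fatty acid oxidation and TCA cycle genes had 8 higher and 0 lower of 21 (median 0.83, percentile 95.36, 98.15 with all peaks of a gene averaged and 80.1 with random lists also matched on fold enrichment), with Dlst at 1.67, Ogdh at 1.93, the carnitine palmitoyltransferase Cpt2 at 0.83 and Hadhb at 1.11 in the authors' deposited table. The respiratory chain list had 6 higher and 0 lower of 20 (percentile 54.59, and 13.58 matched on fold enrichment), with Sdhd at 1.85, Atp5h at 1.68, Uqcrfs1 at 0.90 and Cox6b2 at 0.83 in the authors' deposited table. Mitochondrial dynamics genes had 8 higher and 1 lower of 21 (percentile 75.01), with the helicase Twnk at 1.68, Polg at 1.26, the cristae protein Immt at 1.01 and Pld6 at 0.64 in the authors' deposited table. Integrated stress response genes had 6 higher and 1 lower of 19 (percentile 51.58), with the transcription factor Atf4 at 1.65, Chac1 at 2.79, Eif2s1 at 1.90 and Psat1 at 0.49 in the authors' deposited table.

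Of 53 measured mTORC1 genes 15 were called higher and 4 lower in ClpX cKO, with a median of 0.70 at percentile 93.55, and 90.88 matched on fold enrichment. The inhibitor Tsc2 at 2.98 (chromosome 17, 24596565 to 24596745, fold enrichment 1.71), the kinase Pdpk1 at 1.21, Eif4b at 1.21 and the lysosomal adaptor Lamtor1 at 1.32 were called higher in the authors' deposited table. Autophagy genes had 9 higher and 2 lower of 26 (percentile 65.73), with the receptor Sqstm1 at 1.56, Nbr1 at 1.67, Atg9a at 1.70 and Atg2a at 1.45 in the authors' deposited table. Translation factors had 18 higher and 1 lower of 42 (percentile 81.3, and 21.15 matched on fold enrichment), with Eif4g3 at 1.65, Eif3b at 1.66 and Eif3g at 2.24 in the authors' deposited table. Meiotic recombination genes had 14 higher and 5 lower of 33 (percentile 64.78), with the DNA damage mediator Mdc1 at 1.5, the synaptonemal complex genes Syce3 at 2.20 and Syce1 at 1.82, and H2afx at 0.59 in the authors' deposited table. Meiotic division genes had 8 higher and 0 lower of 27 (percentile 74.09, and 40.01 matched on fold enrichment), with Hspa2 at 0.997, Fzr1 at 2.24 and Aurka at 1.26 in the authors' deposited table. The piRNA list had 8 higher and 0 lower of 15 (percentile 81.12, and 45.16 matched on fold enrichment), with Tdrd7 at 1.56, Piwil2 at 1.33 and Tdrd6 at 0.34 in the authors' deposited table.

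Genes of the m6A machinery were called both ways in ClpX cKO, 5 higher and 7 lower of 24, with a median of -0.15 at percentile 9.16, inside the central 95%. Called lower in the authors' deposited table were the writer subunits Wtap at -2.08, Zc3h13 at -1.36 and Virma at -0.85, the readers Ythdc1 at -1.11, Ythdf3 at -0.54 and Ythdf2 at -0.29, and Meioc, a meiotic partner of the reader Ythdc2, at -0.97. Called higher in the authors' deposited table were Cbll1 at 1.83, the demethylase Alkbh5 at 1.49, Prrc2a at 1.34, Hnrnpc at 1.04 and Rbm15 at 0.39. The peaks of Alkbh5, Prrc2a, Ythdc1 and Virma named here do not overlap those named for ClpP. The same holds for Phb2, Hspa2, Clu, Sdhd, Ubb and Zbtb16. Values of these genes therefore do not compare the same site between the knockouts. Ubiquitin and proteasome genes had 11 higher and 8 lower of 38 (percentile 21.55, and 2.44 matched on fold enrichment), with Ubb at 1.56, Btrc at 1.98 and Psmc2 at 1.19 in the authors' deposited table. Apoptosis genes had 4 higher and 3 lower of 21 (percentile 35.75), with Parp1 at 3.90, Diablo at 1.17, Bad at 1.70 and Mdm4 at -1.80 in the authors' deposited table. For ClpX 1 of the 18 lists lay above the central 95% of random lists and 0 below. At an adjusted p under 0.01 the decreases numbered 659.

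**Figure D3:**
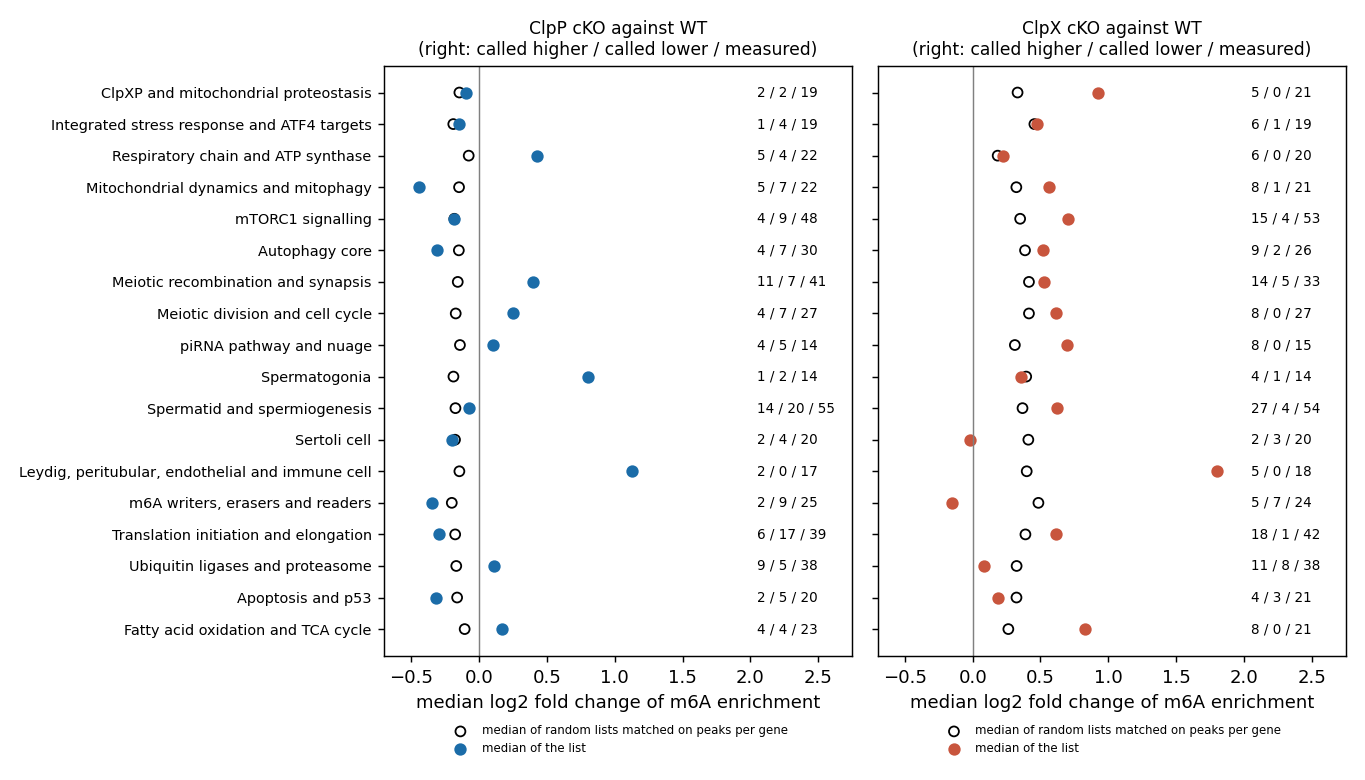
Median log2 fold change of m6A enrichment (x axis) of the 18 gene lists (y axis) in ClpP cKO (left) and ClpX cKO (right) against WT, filled points, beside the median of random lists matched on peaks per gene, open points; the figures at the right give genes called higher, called lower and measured. The list of Leydig, peritubular, endothelial and immune cell markers has the highest median in both, 1.13 and 1.81, or the lowest if the ratio runs the other way.

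The 2 knockouts remove partner subunits of 1 protease, and their comparisons were set side by side. Peaks called higher in both included mt-Nd2 and mt-Nd4, the ATP synthase inhibitor gene Atpif1 (0.65 in ClpP and 1.12 in ClpX), Mns1 (0.81 and 1.20) and Cfap74 (1.88 and 2.71), the last a cilia and flagella gene, per the authors' deposited tables. The paired mt-Nd4 peaks were unlike, with 240 bases and a fold enrichment of 1.99 in ClpP against 869 bases and 88.9 in ClpX. Peaks called lower in both included Fhl4, Gk2, Ldhc, Hspa5 (-0.74 and -0.79) and Malat1 (-0.94 and -0.67) in the authors' deposited tables, the Malat1 peaks sharing bases with another gene's. Of 18709 pairs of overlapping peaks, 416 were called higher in both and 503 lower in both, against 154 and 181 for independent lists. A further 751 pairs were lower in ClpP and higher in ClpX, against 426, and 8 were higher in ClpP and lower in ClpX, against 65.1. Independent lists take every peak as equally likely to be called. Called peaks were longer, with medians of 330 (higher) and 568 bases (lower) for ClpP against 301 over all its peaks. For ClpX these medians were 387, 657 and 300. An excess over independent lists, in any direction, is therefore not by itself a link between the knockouts.

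Of the 1678 pairs called in both, 54.77% went the same way, but at an adjusted p under 0.01 the share was 47.98%. Across all pairs Pearson's r was 0.42 and Spearman's rho 0.38, over peaks, which are not independent replicates. Simulated unchanged knockouts against the shared WT libraries gave an r of 0.464 and the same sign in 66.7% of pairs, where 60.08% was observed. Both simulated values follow largely from the equal shares of variance given to WT and knockout. They are therefore no measure of what the shared WT libraries contributed. The simulation gave 8.95 pairs higher in both, 9.09 lower in both and 0 in opposite directions. The covariance was 0.48 against 0.21 simulated, a difference of 0.27. The simulated errors came from p-values within libraries and hold no spread between libraries or animals. A larger WT deviation would raise the simulated covariance and the pairs called the same way, so these differences do not exclude the shared WT libraries. WT had 1 library of each kind and could not be split. Part or all of the excess over independent lists in the same direction may come from the shared WT libraries.

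**Figure D4:**
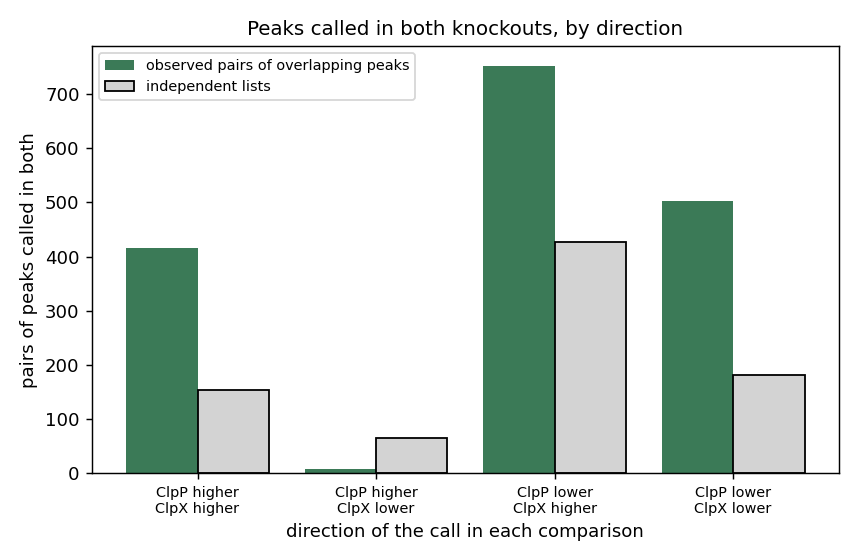
Number of pairs of overlapping peaks called in both comparisons (y axis) by direction in ClpP cKO and ClpX cKO (x axis), observed (green) and for independent lists of the same sizes (grey). The pairs lower in ClpP and higher in ClpX are the most frequent, at 751, and those higher in ClpP and lower in ClpX the fewest, at 8.

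Peaks of the 2 tables were set against each other by position. Of the ClpP peaks 81.36% overlapped a ClpX peak on the same strand by at least 1 base (exact binomial 95% interval 80.86 to 81.85, over peaks), and of the ClpX peaks 84.23% overlapped a ClpP peak (83.76 to 84.69). Fold enrichment of the pairs had a Spearman's rho of 0.81 over peaks. Both tables hold the same WT libraries and give 1 fold enrichment for all libraries of a table, and no value without the shared libraries was computed.

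Peaks lay towards the 3' ends of genes. The midpoint fell in the last 10% of the gene span for 40.9% of 21973 placed peaks in the ClpP table (exact binomial 95% interval 40.25 to 41.56) and 39.26% of 21650 in the ClpX table (38.61 to 39.91), and in the first 10% for 9.36% and 11.4%. Peaks called higher in ClpP were in the last 10% in 37.74% of cases (35.31 to 40.22) and those called lower in 38.41% (36.63 to 40.21). For ClpX these shares were 39.08% (37.42 to 40.77) and 36.57% (33.73 to 39.47), so the intervals of the called classes overlapped within each comparison. Peaks not called were there in 41.59% of cases for ClpP (40.86 to 42.32), above the intervals of both called classes, and in 39.46% for ClpX (38.73 to 40.2). With any part of a peak counted the order changed for every called class but ClpP higher. For ClpP, 46.19% of peaks not called (45.45 to 46.93) stood against 47.64% of those lower (45.8 to 49.48) and 43.87% of those higher (41.37 to 46.4). For ClpX, 43.65% of peaks not called (42.91 to 44.39) stood against 46.51% of those higher (44.8 to 48.23) and 46% of those lower (43.04 to 48.98). Only the ClpX higher interval lay apart from that of peaks not called. Gene spans include introns, and UTRs and coding parts were not placed here.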

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

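The tests of the 3 patterns below were chosen only after the results were seen. The bar for the test within genes was first 50% and was changed to the share in the ClpP comparison after both shares had been seen; the ClpX share lay above either bar. Other tests were also replaced after their values had been seen: the mitochondrial median was first set against single nuclear peaks, the trend test for the opposite calls first counted directions in place of calls, and the test of a deviating WT library first counted the 759 opposite pairs and now takes their share.

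Most called peaks were lower in ClpP cKO and higher in ClpX cKO: 34.43% against 75.06% of called peaks were higher, or 65.57% against 24.94% if the ratio runs the other way, a difference that was not tested. Its size, and the ClpX majority itself, depended on scaling and on the error given to a peak. Called anew after the median of all peaks was subtracted, 36.95% and 56.65% were higher. Pooled errors alone gave 35.65% and 59.93%. Pooled errors with that centring gave 38.62% and 41.88%, which turned the ClpX majority. Each share is to be subtracted from 100% if the ratio runs the other way. On single sites 751 pairs of peaks were called lower in ClpP and higher in ClpX, also not tested as a difference. Of the 1678 pairs called in both, 919 (54.77%) went the same way, but 47.98% at an adjusted p under 0.01 and 48.39% by gene. Pearson's r across all pairs was 0.42, against 0.464 for simulated unchanged knockouts with the shared WT libraries. Examples, chosen after their values were seen, were Dnajb1 (-0.73 and 0.62), Ccdc92 (-0.49 and 0.78), Ehd1 (-0.70 and 0.84), Plec (-0.55 and 0.67) and Tuba3a (-0.40 and 0.78) in the authors' deposited tables.

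For these opposite calls, a deviating WT library would by itself move both comparisons the same way. Yet 759 of the 1678 pairs went in opposite directions, 45.23% (exact binomial 95% interval 42.83 to 47.65). Wrong calls would allow about 10% if the adjusted p of both tables held among these pairs as among all calls. The adjusted p cover all calls of a comparison, and wrong ones may be more frequent among the pairs called in both. The adjusted p also rest on 1 library per arm and leave out the spread between animals. The true share of wrong calls among these pairs is therefore unknown, and 10% is no limit for it. The opposite calls do not decide whether WT was the whole cause, and the part of WT in the calls stays open. The trend with fold enrichment was removed by subtracting the median of each of 5 equal groups in both tables; 88.02% of the 751 pairs then kept both directions, but 52.06% kept both calls (exact binomial 95% interval 48.42 to 55.69), and with pooled errors 33.42% did against 54.99% before that step, so the trend stays open as a cause. Calling all pairs anew after that step gave 428 lower in ClpP and higher in ClpX, against 212 for independent lists, and 40 the other way. Those lists again take every peak as equally likely to be called. The authors' scaling of libraries, a difference between the knockout libraries in capture or handling, and a real difference between loss of ClpP and loss of ClpX stay open, with 1 library each.

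The fall of ClpX log2 fold changes with fold enrichment may have a technical source. Counting noise of the shared WT libraries would weaken in well supported peaks and appear in ClpP too, but Spearman's rho in the best supported peaks was -0.51 for ClpX (95% bootstrap interval -0.53 to -0.49) and -0.0062 for ClpP. Differences between genes in input abundance would not act within a gene, yet in 63.6% of 1882 genes (61.38 to 65.78) the weakest well supported peak had a higher log2 fold change than the strongest, against 58.19% for ClpP (55.96 to 60.39), a narrow gap between intervals that argues against abundance as the whole cause. A less selective immunoprecipitation in the ClpX cKO library needs such a shift within genes, and the same 63.6% goes with it. The ClpP share also lay above 50% with its whole interval, so part of the shift was not particular to ClpX. The shared WT libraries were not tested as its source, and the 63.6% does not single out the ClpX cKO library. The reading as a less selective library also rests on the direction taken for the ratio. If the ratio runs the other way, the weakest peak had the lower value in 63.6% (ClpX) and 58.19% (ClpP) of these genes. Both rho then change sign, and the shift would not point to a less selective ClpX cKO library. A change of m6A itself was not tested apart from a less selective immunoprecipitation and stays open.

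For mitochondrial transcripts, a carry-over like that of weak nuclear peaks is one candidate explanation. In ClpX the 6 mitochondrial peaks with a fold enrichment under 10 had a median log2 fold change of 2.215 (1.48 to 2.74), at percentile 100 of 10000 random sets of as many from 780 nuclear peaks of like enrichment and support, whose medians reached 1.235 at the upper end of their central 95%. In ClpP the median of 0.787 over 7 peaks lay above the corresponding 0.0929, at percentile 100 as well. Both comparisons share the WT libraries, so their agreement is no second observation, and a deviating WT library was not tested for this pattern. Mitochondrial peaks lie on 1 small genome and may move together, while the random sets drew separate nuclear peaks. The percentiles therefore argue only weakly against the carry-over seen in nuclear peaks as the whole cause. Taken singly, 5 of 6 ClpX peaks and 6 of 7 ClpP peaks lay above the 95th percentile of these nuclear peaks. A change in the abundance of mitochondrial RNA in the input libraries cannot be told apart from a change in its capture, since 0 libraries had read counts per transcript here.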

How the results depend on the processing

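Alternatives chosen only after the results were seen were doubled p-values, peaks without shared bases, centring within 5 equal groups of fold enrichment, calling anew with or without centring or pooled errors, and random lists also matched on fold enrichment or on peak support. Calling anew with errors pooled over peaks of like support gave ClpX 3362 higher and 2248 lower (59.93% higher), and after centring it turned the majority: 2266 and 3145 (41.88%) on the median of all peaks, 2228 and 2534 (46.79%) within groups of enrichment. For ClpP these shares were 35.65%, 38.62% and 41.36%. With the errors of called peaks taken from their own p, centring on the median gave 36.95% for ClpP and 56.65% for ClpX (1922 lower), and within groups 37.31% and 58.77% (2021 higher). The other alternatives kept both majorities, but centring without new calls could only turn signs. At an adjusted p under 0.01 the ClpP increases numbered 979 against 1626 and the ClpX decreases 659 against 1185, and 29.58% and 80.24% of calls were higher. Unadjusted p gave 2812 ClpP increases (39.26% higher) and 2111 ClpX decreases (69.93%). An absolute log2 fold change of at least 1 left 1122 of 3096 ClpP decreases (49.16% higher). The share of higher calls was also 32.01% (ClpP) and 72.5% (ClpX) at a fold enrichment of at least 2, 31.86% and 77.37% with p doubled, 36.18% for ClpP without shared bases, 72.47% for ClpX counted by gene, and 71% for ClpX centred within groups of enrichment. If the ratio runs the other way, each share here is to be subtracted from 100%. The counts at other thresholds follow from the thresholds; for the shares the cause was not tested.

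Of the pairs called in both, 47.98% went the same way at an adjusted p under 0.01 and 48.39% by gene, which reverses the majority of 54.77%. At 0.01 there were 216 pairs higher in both, 259 lower in both and 0 higher in ClpP and lower in ClpX; by gene the last numbered 63 against 8. Called anew after centring within groups, 191 pairs were higher in both, 428 lower in ClpP and higher in ClpX and 40 the other way, with 57.57% the same way. The cause was not tested. With an overlap of at least 50% of each peak, 72.18% and 73.55% of peaks were found in the other table. Counting any part of a peak, the last 10% of the gene span held 46.22% of ClpP peaks (higher 43.87%, lower 47.64%) and 44.21% of ClpX peaks (higher 46.51%, lower 46%), as a wider target must.

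Matching on peak support put 5 ClpP lists above the central 95% in place of 2, with the recombination list at percentile 99.68, spermatids at 98.13 and the piRNA list at 97.51. Gene averages put 2 ClpX lists above in place of 1, and matching on fold enrichment put 1 below in place of 0, ubiquitin and proteasome genes at percentile 2.44. The cause was not tested. The list of Leydig, peritubular, endothelial and immune cell markers lay above the central 95% in both comparisons under all 5 ways of matching or averaging. Those ways reuse the same libraries, and both comparisons share the WT libraries, so this agreement is no second observation. Of 220 named peak values, 1 changed sign: the Tubb4b peak at 25222160, called higher in ClpX, at -0.36 after centring within groups of enrichment. Calls were lost by 99 at an absolute log2 fold change of at least 1, 34 at a fold enrichment of at least 2 and 14 at an adjusted p under 0.01. Among the 34 were mt-Rnr1, mt-Rnr2, mt-Nd4, Prm1, Ubb and Serf1 in ClpP, and Tsc2, Clpb, Parp1, Hspa9, Eif3g and Insl3 in ClpX. When called anew, with such errors of their own, 6 lost their call after centring on the median and 17 within groups.

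No paired analysis was possible because each group held 1 library, and leaving out a library was ruled out for the same reason. What depth limits is unknown here.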

Other observations

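The gene families and single peaks in this part were chosen only after their values were seen, and no test of a hypothesis is reported in it. Replication-dependent and linker histone genes were called higher in ClpX cKO in 24 of 41 cases and lower in 3, with a median log2 fold change of 0.77 (percentile 99.51 of random lists matched on peaks per gene, and 81.06 when also matched on fold enrichment). In ClpP cKO 2 of 26 were higher and 8 lower, with a median of -0.33 (percentile 13.95, and 5.59 with that matching). Tubulin genes likewise had 7 higher and 0 lower of 11 in ClpX (percentile 96.46, and 93.86 with that matching) and 2 higher and 6 lower of 10 in ClpP (29.45 and 16.66). Dynein heavy chain genes, motors of sperm flagella and cilia, had medians of 1.30 in ClpX and 0.70 in ClpP over 11 genes each (percentiles 90.51 and 84.32, and 60.95 and 67.77 with that matching). Cytosolic ribosomal protein genes had 9 higher and 1 lower of 31 in ClpX (percentile 40.62, and 3.61 with that matching) and 5 higher and 8 lower of 26 in ClpP (percentile 97.15, and 93.66 with that matching). Histone genes resemble each other in sequence, as do tubulin genes, so the gene of a read is uncertain there.

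Genes of the sex chromosomes had medians on opposite sides of 0. In ClpX the median of all peaks was itself 0.239, so a median above 0 there does not set chromosome X apart from other genes. Genes on chromosome X had a median log2 fold change of 0.27 over 460 genes in ClpP (percentile 100 with either matching, though 32 were called higher and 31 lower) and 0.33 over 423 genes in ClpX (percentile 66.38, and 99.78 when also matched on fold enrichment, with 52 higher and 19 lower). Genes on chromosome Y had a median of -0.52 over 33 genes in ClpP (percentile 1.55, and 3.88 when also matched on fold enrichment, inside the central 95%) and -1.32 over 27 genes in ClpX (percentile 0 with either matching), although 0 in ClpP and 1 in ClpX, higher, were called.

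Single genes held peaks that were called in opposite directions, 246 genes in ClpP and 166 in ClpX. Rb1cc1, which encodes an autophagy initiation scaffold, had a peak called lower in ClpP at 6238427 to 6241045 of chromosome 1 (-0.65) and peaks called higher at 6248142 to 6262860 (0.24, fold enrichment 16.9) and at 6274310 to 6274430 (1.93, fold enrichment 1.35) in the authors' deposited table. Along genes with at least 2 placed peaks, the last peak exceeded the first in log2 fold change in 54.4% of 5656 ClpP genes (exact binomial 95% interval 53.09 to 55.71) and 48.78% of 5552 ClpX genes (47.45 to 50.1). If the ratio runs the other way, these are the shares of genes whose last peak lay below the first. The fold enrichments of mt-Co1 (91.4) and mt-Nd4 (88.9) in the authors' deposited ClpX table stood far above the 1.67 to 6.10 of the other mitochondrial peaks there.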
